A study of Mus musculus with 30 samples.

How the data were processed

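The study measured RNA on 30 Affymetrix Mouse Genome 430 2.0 arrays. Of these, 22 came from neurospheres grown from the ganglionic eminences of E14.5 mouse embryos that lacked Ink4a/Arf and carried 2, 1 or 0 working copies of Olig1/2. Per the labels the cells received EGFRvIII by retrovirus and puromycin selection, and part of the cultures then received Olig2 or GFP by retrovirus and blasticidin selection. The other 8 arrays came from forebrain and spinal cord of 4 E18.5 embryos. The tissue labels name the Olig2 genotype, while the series design names Olig1/2, and the genotypes are called null and heterozygous here. The passage at harvest of each array was not stated, and the background was mixed.

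The deposited values are MAS5 signals, with the unit intensity on a linear scale, which the authors scaled so that the mean without the lowest and highest 2% of probe sets was 500 on each array. The version of MAS5 is not given in the sources used here. Detection calls were not used here. Median signals ran from 128.9 to 217.4 and correlations between arrays of a group from 0.925 to 0.945. The number of arrays limits the precision. The labels give no batch that could be compared.

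Of 45101 probe sets, 64 were controls, 34958 had 1 gene symbol, 932 had several and 9211 had none, controls included. Those with 1 symbol stood for 18193 genes, and each gene was read from the probe set of highest mean log2 signal over all 30 arrays. The RefSeq table of assembly GRCm38.p6 matched 34754 of these probe sets by Entrez identifier, changed 0 symbols, and gave the chromosomes. Values were log2 of the signal plus 16. There were 4 sets of arrays: 12 untransduced neurospheres, 10 neurospheres with GFP or Olig2 virus, 10 arrays for the vector and 8 tissue arrays. In each set a gene was tested when its signal reached the array's median in as many arrays as the smallest group holds. Untransduced here means without GFP or Olig2 virus, as the labels give every neurosphere culture the EGFRvIII virus.

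Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment per comparison. A gene was called at an adjusted p under 0.05, and differences are log2. The comparisons were null against both, wild-type and heterozygous cultures, heterozygous against wild-type, Olig2 against GFP in null and heterozygous lines with their difference, null against heterozygous with GFP, GFP against untransduced, and null against heterozygous in each tissue with their difference, and spinal cord against forebrain. Line numbers and embryo numbers link arrays, but the correlations that this link gave, from -0.10 to 0.13, were low, and the arrays were treated as unpaired with a block for the line or embryo as an alternative. In all, 30 gene lists for cell types, signalling, stress and the neighbours of Olig1/2 were tested with camera (preset correlation 0.01, and with an estimated one), and 528 of their 568 memberships had a probe set. The data.table package (1.17.8) read the files, and plots were drawn with python 3.11.15 and matplotlib 3.10.9.

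The groups, comparisons, lists, main settings and most alternatives were chosen before the data were examined. The genes to name were Olig1, Olig2, Id4 and Cdkn1a, the 10 called genes with the largest rise and the 10 with the largest fall per comparison (the 3 of smallest p each way where no gene was called), and up to 4 members of smallest p from each list described. Alternatives were other pseudocounts (1 and 64), another filter or none, quantile or 75th percentile scaling, all probe sets, probe sets without cross-hybridisation, array weights, no trend, 2-group fits, a log2 difference of at least 1, the block, and each array left out in turn. Added after the values were seen were a term for sex, untransduced arrays as the control for Olig2, a Gapdh covariate, the removal of chromosome 15, and a reading of all probe sets of genes called in both tissues. The pipeline was tested on simulated data with the signals of these arrays and 200 changed genes. Of 2-fold changes 84% were recovered in null against Olig-expressing cultures, 47% for Olig2 in null lines and 59% in spinal cord, and of 4-fold changes 95%, 84% and 85%, with 0 of the wrong sign.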

Results

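Olig1 and Olig2 are neighbouring genes for basic helix-loop-helix transcription factors of the oligodendrocyte lineage, and Id4 encodes an inhibitor of such factors. The neurosphere arrays ask which transcripts depend on Olig1 and Olig2 in neural progenitors that express the mutant receptor EGFRvIII. In 6 null cultures the Id4 signal averaged 3032 ± 333 (SD, n = 6), against 158 ± 42.7 (SD, n = 3) in wild-type and 128 ± 68.4 (SD, n = 3) in heterozygous cultures. Id4 rose by 4.33 ± 0.20 (SE) on the log2 scale against the 6 Olig-expressing cultures (adjusted p 2.8e-08), and each null array lay above each of these 6. Olig1 fell by 1.61 ± 0.10 (SE) and Olig2 fell by 0.80 ± 0.14 (SE), with adjusted p 2.1e-07 and 0.0028. Signal of both probe sets remained in the null cultures, at 8068 ± 1018 for Olig1 and 8302 ± 2120 for Olig2 (SD, n = 6). Where these probes lie relative to the deleted sequence is not given in the sources used here. Cdkn1a, the p53 target that encodes the cell-cycle inhibitor p21, was not called (-0.24, adjusted p 0.44).

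**Figure D1:**
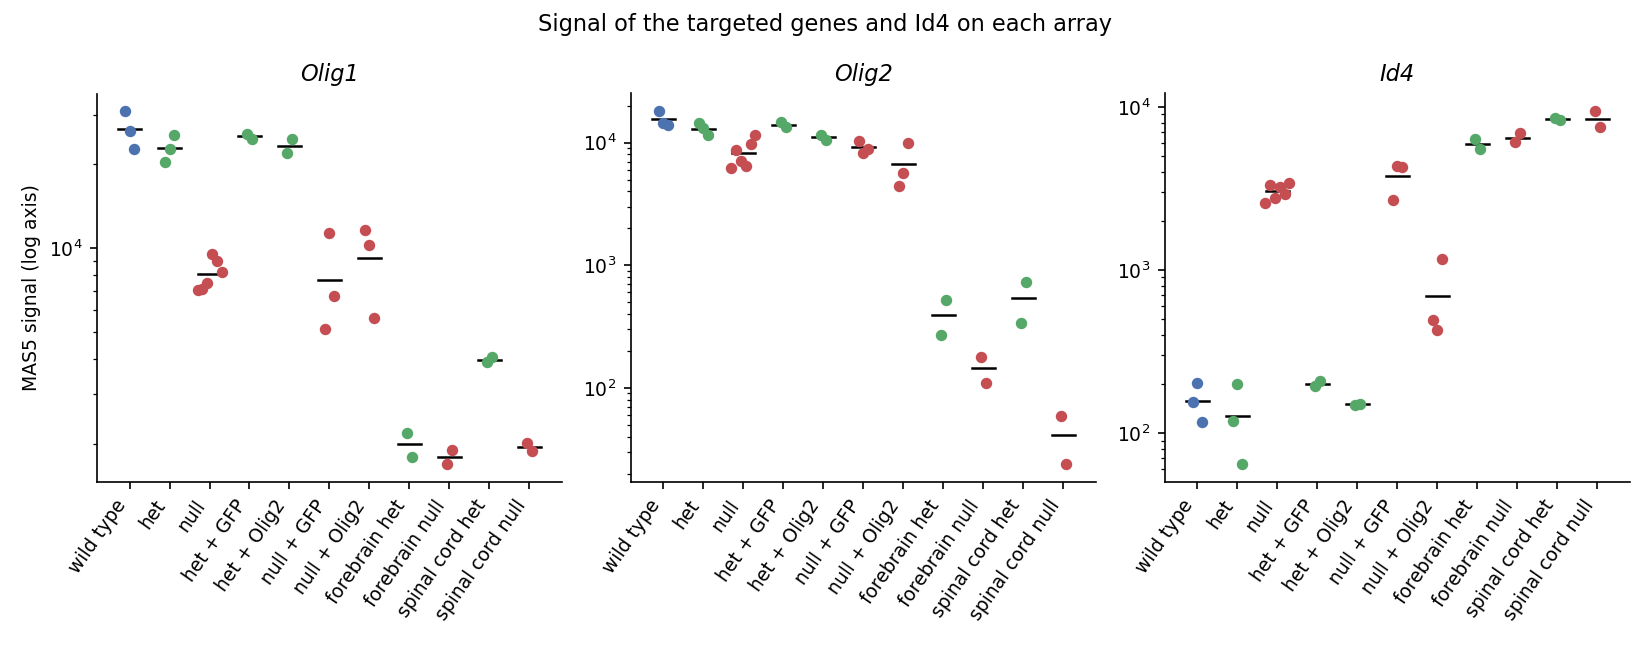
Array signal (log axis) of Olig1, Olig2 and Id4 on each array, by group, with a bar at each group's mean; blue is wild type, green heterozygous and red null. Among untransduced neurospheres the Id4 mean is 3032 in null cultures and 158 in wild-type cultures.

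Of 12022 genes tested between null and Olig-expressing neurospheres, 1000 were called, of which 522 rose and 478 fell, and 315 of the calls had a log2 difference of at least 1 in size. The muscle cofactor gene Lmcd1 rose by 4.41 (SE 0.24), from 266 ± 110 to 5553 ± 1017 (SD, n = 6 each). Rgs16, which limits G-protein signalling, rose by 3.99, and the extracellular matrix gene Thsd4 rose by 3.83. The calcium-channel subunit gene Cacng5 rose by 3.37 and the oligodendrocyte receptor gene Gpr37 rose by 3.25. The neural adhesion gene Chl1 fell by 3.60 (SE 0.42), from 2157 ± 1609 to 128 ± 32.6. The axon growth gene Gap43 fell by 3.04, the carbonic anhydrase family gene Car8 fell by 2.83, and the potassium channel gene Kcnd2 fell by 2.63. These 9 genes and Id4, Olig1 and Olig2 were called whichever of the 12 arrays was left out. A high signal of Xist, which marks cells with 2 X chromosomes, was present in 2 of 3 wild-type, 2 of 3 heterozygous and 2 of 6 null cultures, and a term for it gave 1034 calls. The Y-linked gene Eif2s3y was among the genes called higher in the null cultures (2.82 to 3.78 over all arrays left out). Its call ended without 9 of the 12 arrays left out in turn. Eif2s3y did not follow sex on each array. Wild-type line 2 had a low Xist signal (9.6) and 480.3 for the Y-linked gene Kdm5d, but 1.8 for Eif2s3y.

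Astrocyte genes as a list were higher in the null cultures. Of 24 tested, 9 rose, 1 fell and 14 had no call, and 11 rose and 1 fell when adjusted over the list alone (camera adjusted p 0.0020, and adjusted p 0.388 with an estimated correlation). Glutamine synthetase, Glul, rose by 1.74, Cst3 by 0.58, Sparcl1 by 0.55 and the glial fate factor Nfia by 0.50. Sparcl1 was no longer called in a fit of the 6 null against the 6 Olig-expressing arrays as 2 groups. Of the 28 lists tested in this comparison the astrocyte list was the 1 past the threshold. Oligodendrocyte precursor genes did not move as a list (adjusted p 0.929), with 3 of 17 rising and 1 falling. The precursor proteoglycan gene Cspg4 fell by 1.84 and Rlbp1 rose by 1.25, while the early oligodendrocyte gene Bcas1 fell by 1.91. Among neural stem genes, where 6 of 21 rose and 2 fell (adjusted p 0.0575), the Hedgehog effector Gli2 rose by 2.67, Sox1 by 1.22 and Lhx2 by 0.99. The Notch ligand gene Dll1 fell by 1.28. Of 16 BMP and Id genes 4 rose and 2 fell (adjusted p 0.0520), and Smad1 rose by 0.70, Smad5 rose by 0.55 and Bmp7 fell by 0.75.

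Against the 3 wild-type cultures alone, 806 genes were called in the null cultures, 464 of which rose and 342 fell. Lmcd1 rose by 4.68, Id4 by 4.15 and the ubiquitin ligase gene Trim2 by 3.29. Gap43 fell by 4.33, Chl1 fell by 3.35, Olig1 fell by 1.72 and Olig2 fell by 0.93 (adjusted p 0.0052). These 7 genes were called without each array in turn. The total was 478 without wild-type line 2 and 529 without wild-type line 3. No list of the 28 passed the threshold.

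Against the 3 heterozygous cultures, 422 genes were called, of which 258 rose and 164 fell. Id4 rose by 4.51 and Lmcd1 by 4.13, and both kept their calls without each array in turn, as did Chl1, which fell by 3.86. The chromatin gene Hmga2, active in fetal stem cells, fell by 2.82 and kept its call in the same way. The lipid carrier gene Apoe rose by 2.95, with 2.81 and no call without heterozygous line 15, and 2.94 and no call without heterozygous line 26. Olig1 fell (adjusted p 7.4e-06), while Olig2 was not called (-0.68, adjusted p 0.051), though it passed without null line 21 (-0.73) or null line 24 (-0.78). The count was 242 without heterozygous line 11 and 272 without heterozygous line 15.

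In the same comparison with heterozygous cultures, astrocyte genes were higher as a list (adjusted p 1.2e-04, and adjusted p 0.349 with an estimated correlation), with 5 of 24 called up, 0 down and 19 with no call, and 11 up adjusted over the list alone. Neural stem genes were higher (adjusted p 0.0357, and adjusted p 0.177 with an estimated correlation; 3 rose, 2 fell and 16 had no call of 21; adjusted over the list alone, 6 rose and 2 fell), including Gli2 and Sox1. BMP and Id genes (2 rose, 0 fell and 14 had no call of 16; adjusted over the list alone, 3 rose and 2 fell) and neuronal genes (1 rose, 0 fell and 15 had no call of 16; adjusted over the list alone, 1 rose) each had adjusted p 0.0259, and adjusted p 0.150 with an estimated correlation, and Smad1 was among the former. Hypoxia and glycolysis genes were lower (adjusted p 0.0367, and adjusted p 0.879 with an estimated correlation; 1 rose, 2 fell and 13 had no call of 16; adjusted over the list alone, 1 rose and 4 fell).

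Heterozygous and wild-type neurospheres differed at 4 genes, with 3 higher and 1 lower in the heterozygous cultures. The matrix protein gene Sparcl1 rose by 0.88 (adjusted p 0.016). Efhd2 rose by 1.36, Rhbdf1 rose by 0.95 and Klhl23 fell by 1.03, each with adjusted p 0.043. Id4 (-0.36), Olig1 (-0.22) and Olig2 (-0.25) were not called. In limma 799 genes had an unadjusted p under 0.05. The count was 0 without wild-type line 3, heterozygous line 11 or heterozygous line 15, and each of these, and wild-type line 2, ended the call on Sparcl1 (0.84 to 0.94 over all arrays left out). It was 1 without wild-type line 2, heterozygous line 26 or any of null lines 13, 14, 21 and 24, and 8 without null line 16.

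In 3 null lines a retrovirus carrying Olig2 was compared with a virus carrying GFP, which asks what Olig2 alone restores. Of 12458 genes tested 982 were called, of which 404 rose and 578 fell. Hmga2 rose by 3.91 ± 0.23 (SE), from 196 ± 64.4 to 3107 ± 608 (SD, n = 3 each; adjusted p 1.8e-05). Kcnd2 rose by 3.96, the intracellular calcium channel gene Ryr3 by 3.73 and Car8 by 3.28. Id4 fell by 2.52 ± 0.32 (SE), from 3766 ± 949 to 697 ± 411 (SD, n = 3 each; adjusted p 0.0020). The MAP kinase phosphatase gene Dusp4 fell by 3.61, from 5480 ± 1230 to 454 ± 179, the integrin gene Itga8 fell by 3.44 and the chemokine receptor gene Cxcr4 fell by 2.49. The calls on these 8 genes held without each of the 10 arrays in turn. Rgs16 fell by 3.79, but was not called without GFP line 13 (-3.62) or Olig2 line 12 (-3.86). The Notch ligand gene Dll1 rose by 1.62. The signal of the Olig2 probe set did not rise with the Olig2 virus (-0.53, adjusted p 0.18; 6720 ± 2918 with the virus and 9168 ± 1016 with GFP, SD, n = 3 each), and the position of that probe set relative to the viral insert is not given in the sources used here. The antigen gene Ly6e, on chromosome 15, fell by 3.32, but was at 0.05 when probe sets marked as cross-hybridising were left out. With arrays scaled to their 75th percentile the median of all genes moved from 0.03 to -0.09, and 1328 genes were called, of which 303 rose and 1025 fell.

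**Figure D2:**
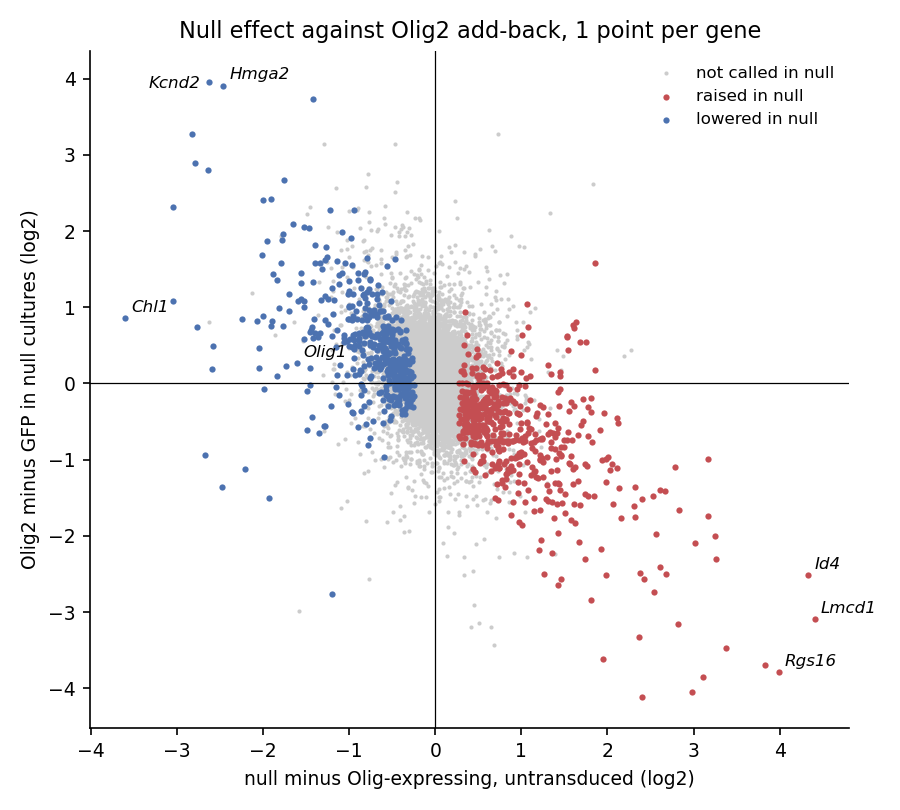
Each point is a gene, with the log2 difference of null against Olig-expressing untransduced neurospheres on the x axis and of Olig2 against GFP virus in null neurospheres on the y axis; red genes were raised in the null cultures, blue genes lowered and grey genes not called. Id4 lies at 4.33 and -2.52, and across 11789 genes the Pearson correlation was -0.445.

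Of 519 genes raised in the untransduced null cultures and tested here, 172 fell with Olig2, 2 rose and 345 had no call, where 25.4 falls would come from an unrelated set of that size. With or without a call 460 were lower (88.6%, against 48.0% of all genes). Of 471 lowered genes, 105 rose, 2 fell and 364 had no call, where 15.9 rises would come from such a set, and 369 were higher (78.3%, against 52.0% of all genes). Camera gave p 1.9e-32 for the raised and 1.1e-13 for the lowered set, and 0.0026 and 0.0051 with an estimated correlation. Across genes, which are not independent replicates, Pearson's r was -0.445 and Spearman's rho was -0.342. Id4, Lmcd1, Cxcr4 and Dusp4 were among the genes that rose in the null and fell with Olig2, and Kcnd2, Car8, Hmga2 and Pcdh7 among the reverse. The astrocyte genes, higher as a list in the null cultures, were not lower as a list with Olig2. Of 24 tested 5 rose, 1 fell and 18 had no call, 8 rose and 2 fell adjusted over the list alone, and the median was 0.44 (camera adjusted p 0.140, and adjusted p 0.540 with an estimated correlation).

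Target genes of p53 were lower with Olig2 in the null lines. Of 18 tested, 0 rose, 11 fell and 7 had no call, while 1 rose and 13 fell when adjusted over the list alone (camera adjusted p 2.0e-06, and adjusted p 0.418 with an estimated correlation). The atypical cyclin gene Ccng1 fell by 1.48, the zinc-finger gene Zmat3 by 1.18, Trp53inp1 by 1.09 and the p53 ligase gene Mdm2 by 0.77. Cdkn1a fell by 0.81 ± 0.17 (SE, adjusted p 0.020), and was not called without GFP line 12 (-0.74), GFP line 13 (-0.65), Olig2 line 12 (-0.73) or Olig2 line 13 (-0.83). Hypoxia and glycolysis genes were higher (adjusted p 2.2e-06, and adjusted p 0.418 with an estimated correlation), with 10 of 16 up, 0 down and 6 with no call, and 11 up adjusted over the list alone. The mitophagy receptor gene Bnip3 rose by 2.58, Pdk1 by 1.72, Vegfa by 1.39 and the glucose transporter gene Slc2a1 by 1.17. Stress and immediate early genes passed with the culture line as a block (adjusted p 0.017, higher), and not without it (0.052), and in the blocked fit had adjusted p 0.619 with an estimated correlation.

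The count of 982 was 304 without Olig2 line 12, 358 without Olig2 line 13, 527 without GFP line 13 and 554 without GFP line 14. The Gapdh 3'/5' log2 signal ratio, a measure of RNA integrity, was 0.43 on GFP line 13, -0.09 on GFP line 12 and -0.04 on GFP line 14, and averaged -0.22 ± 0.03 on the null Olig2 arrays (SD, n = 3). Against the untransduced arrays of the same lines 380 genes were called, 276 of them among the 982 with the same sign. Over the 982 genes, chosen by the GFP comparison, the median ratio of the difference against untransduced to that against GFP was 0.71. The quartiles of this ratio were 0.51 and 0.90. In that comparison Id4 fell by 2.16 and Hmga2 still rose, while Kcnd2 (2.74), Pcdh7 (1.42), Mdm2 (-0.57), Cdkn1a (-0.36), Pdk1 (0.95) and Slc2a1 (0.86) were no longer called. With the Gapdh ratio as a covariate 227 genes were called, and Kcnd2 (4.09), Rgs16 (-3.32), Dll1 (1.52), Trp53inp1 (-0.81), Cdkn1a (-0.58) and Slc2a1 (0.86) were not among them. The median of the p53 target list was -0.55 against untransduced and -0.73 against GFP arrays, and that of the hypoxia and glycolysis list was 0.31 and 0.86.

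Expression by chromosome was not even across cultures. Genes of chromosome 15, which holds Arc, Ly6e and Gpaa1, had a median log2 deviation of 0.14 to 0.26 on 7 of the 22 neurosphere arrays, all 3 null Olig2 arrays among them, and the other neurosphere arrays ran from -0.13 to 0.05. Of 498 genes of chromosome 15 tested between Olig2 and GFP in the null lines, 31 rose and 11 fell, and 939 genes were called without that chromosome. On wild-type line 3 genes of chromosome 19 had a median deviation of 0.26.

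**Figure D3:**
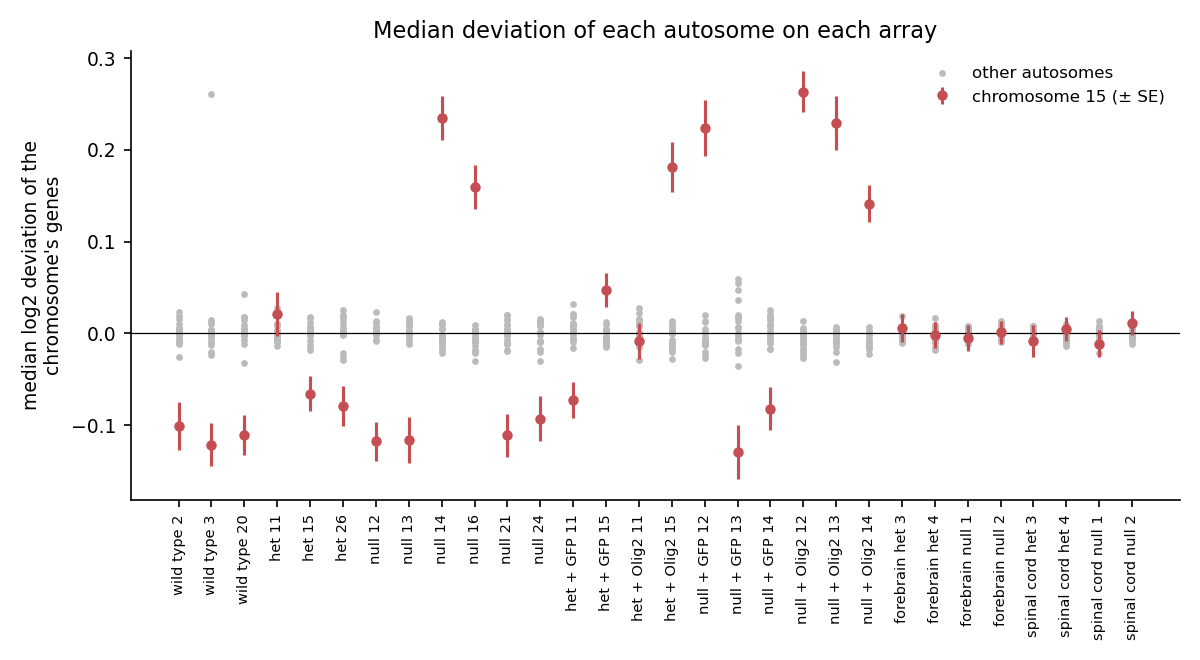
Median log2 deviation of the genes of each autosome on each of the 30 arrays, with chromosome 15 in red with its standard error and the other autosomes in grey. On 7 neurosphere arrays chromosome 15 lies between 0.14 and 0.26.

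In the 2 heterozygous lines, Olig2 against GFP virus gave 0 calls in limma, with 484 genes at an unadjusted p under 0.05. The genes of smallest p included Ddit4l, an inhibitor of mTOR signalling (1.95, adjusted p 0.31), and Vegfa (0.96). Id4 differed by -0.39. The signal of the Olig2 probe set did not rise here either (-0.34, adjusted p 0.9999; 11052 ± 832 with the Olig2 virus and 14021 ± 1041 with GFP, SD, n = 2 each). Hypoxia and glycolysis genes were higher as a list (adjusted p 0.0010, and adjusted p 0.872 with an estimated correlation), with 0 of 16 called, and 3 up adjusted over the list alone. Stress and immediate early genes were also higher (adjusted p 0.0016, and adjusted p 0.872 with an estimated correlation), with 0 of 16 called in either way. The genes lowered in the null cultures were higher with Olig2 here too (camera p 8.0e-08, and 0.021 with an estimated correlation). The genes raised there were lower (9.7e-04, and 0.219). The count was 4 without the Olig2 array of line 11 and 1 without that of line 15.

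The Olig2 effect differed between null and heterozygous lines at 7 genes, 3 with a more positive and 4 with a more negative effect in the null lines. Hmga2 differed by 4.17, as the value was 3.91 in the null lines and -0.26 in the heterozygous lines. The secreted olfactomedin gene Olfml3 differed by 3.82 and Itga8 by -3.36. Both kept their calls with the culture line as a block, which gave 4 calls, but lost them without GFP line 15 (3.31 to 4.33 for Olfml3 and -3.64 to -3.08 for Itga8 over all arrays left out), Olig2 line 11 or 15, or null GFP line 14. Hmga2 was called without each array. Gpaa1 on chromosome 15 (2.41), Ptprd (-2.71), Dipk2a (-1.43) and Lrpap1 (-1.36) were not called with that block, nor without 6, 4, 9 and 7 of the 10 arrays left out in turn. The difference for Id4 was -2.13 (adjusted p 0.19). Target genes of p53 were lower as a list (adjusted p 3.1e-07, and adjusted p 0.466 with an estimated correlation), with 0 of 18 called and 8 down adjusted over the list alone. Hypoxia and glycolysis genes were higher (adjusted p 0.021, and adjusted p 0.605 with an estimated correlation), with 0 of 16 called and 2 up adjusted over the list alone. The count was 4 without heterozygous GFP line 11, 2 without heterozygous Olig2 line 11, 15 without null GFP line 12 and 34 without null Olig2 line 14. It was 1 without null GFP line 14 or without either array of heterozygous line 15.

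Between null and heterozygous lines that both carried the GFP virus, 212 genes were called, of which 144 rose and 68 fell. Id4 rose by 4.09 (adjusted p 4.1e-04), Cxcr4 rose by 3.39 and Hmga2 fell by 3.85, and these 3 were called without each array in turn. Kcnd2 fell by 4.55, but was not called without GFP line 11 or 15 of the heterozygous lines (range -5.03 to -4.10). Olig1 fell by 1.78 (adjusted p 0.017), with a range of -2.10 to -1.53 and no call without either of these arrays or null GFP line 14. Olig2 was not called (-0.62, adjusted p 0.28). Target genes of p53 were higher in the null lines (adjusted p 2.1e-04, and adjusted p 0.717 with an estimated correlation), with 1 of 18 up, 0 down and 17 with no call, and 7 up adjusted over the list alone. Hypoxia and glycolysis genes were lower (adjusted p 0.0064, and adjusted p 0.717 with an estimated correlation), with 1 of 16 down, 0 up and 15 with no call, and 1 up and 7 down adjusted over the list alone. The Gapdh ratio of GFP line 13 (0.43) lay above those of GFP line 12 (-0.09) and GFP line 14 (-0.04). The count was 42 without heterozygous GFP line 11, 41 without heterozygous GFP line 15 and 122 without null GFP line 14.

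The GFP virus itself was set against untransduced cultures of the same 5 lines, as a measure of what this virus and blasticidin selection change. Both sets carried the EGFRvIII virus after puromycin selection, and passage at harvest was not stated per array. Of 12427 genes 3 were called, and all 3 fell: the GABA receptor gene Gabra2 (-1.35), the cytokine signalling inhibitor gene Socs3 (-1.19) and the inflammatory factor gene Cebpd (-1.08). With the culture line as a block 0 were called by limma, and 1566 genes had an unadjusted p under 0.05 without it. Cell-cycle genes were higher with GFP as a list (adjusted p 5.7e-07, and adjusted p 0.517 with an estimated correlation), with 0 of 29 called and 10 up adjusted over the list alone. Stress and immediate early genes (5.7e-07; 0 of 16 called, 7 down adjusted over the list alone) and hypoxia and glycolysis genes (3.6e-06; 0 of 16 called, 4 down) were lower, both with adjusted p 0.348 with an estimated correlation. Mesenchymal glioma genes (1.5e-04; 0 rose, 1 fell and 18 had no call of 19, 4 down adjusted over the list alone), microglial genes (0.014; 0 of 3 called, 1 down) and EGFR and MAPK response genes (0.033; 0 of 19 called, 1 down) were lower as well. With an estimated correlation the mesenchymal and microglial lists had adjusted p 0.348 and the EGFR and MAPK list had adjusted p 0.517. The Gapdh ratio was higher with GFP than without it in lines 11 (-0.14 and -0.22), 12 (-0.09 and -0.21), 13 (0.43 and -0.13) and 14 (-0.04 and -0.23), and lower in line 15 (-0.24 and -0.21). The count was 0 without untransduced heterozygous line 11, where Gabra2 was at -1.27, 5 without GFP line 14, and 1 without untransduced line 12 or 13 or GFP line 11 or 13.

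Forebrain and spinal cord of E18.5 embryos show the loss of Olig in tissue, at a stage when the first spinal oligodendrocytes mature. In spinal cord, 16 of 12342 genes were called between 2 null and 2 heterozygous embryos, of which 7 rose and 9 fell. Gpr17, a receptor of differentiating oligodendrocyte precursors, fell by 5.74 ± 0.37 (SE), from 1846 ± 11.2 to 19 ± 4.88 (SD, n = 2 each; adjusted p 1.3e-04). The myelin gene Mbp fell by 2.95, from 3046 ± 490 to 389 ± 136 (adjusted p 0.0013). Both were called without each of the 8 arrays in turn. Without the trend 1 gene was called in spinal cord, so at least 1 of these 2 calls ended there. Olig2 fell by 3.24, from 536 ± 283 to 41.2 ± 24.5 (adjusted p 0.043), the myelin enzyme gene Cnp fell by 1.15 and Olig1 fell by 1.03. The neurofilament gene Nefm fell by 1.15 and the lectin gene Chodl fell by 1.40. As lists, spinal motor neuron genes (adjusted p 0.059; 0 of 14 called, 1 down adjusted over the list alone) and neuronal genes (0.563; 1 rose, 1 fell and 20 had no call of 22; adjusted over the list alone, 1 rose and 2 fell) did not pass. The matrix genes Col15a1, Dcn and Col4a1 rose by 1.65, 0.99 and 0.69. Id4 was not called (0.00). The calls on Olig2 (-2.79), Cnp (-0.94), Olig1 (-0.98), Nefm (-1.06), Chodl (-1.43), Col15a1 (1.66), Dcn (0.90) and Col4a1 (0.68) ended without the spinal cord of null embryo 2, where the count was 2. Those on Olig2, Chodl, Col15a1 and Dcn ended without any 1 of the 4 spinal cord arrays, with Olig2 between -3.79 and -2.69 over all arrays left out. The count was 10 without the spinal cord of null embryo 1 and 5 without that of heterozygous embryo 3.

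**Figure D4:**
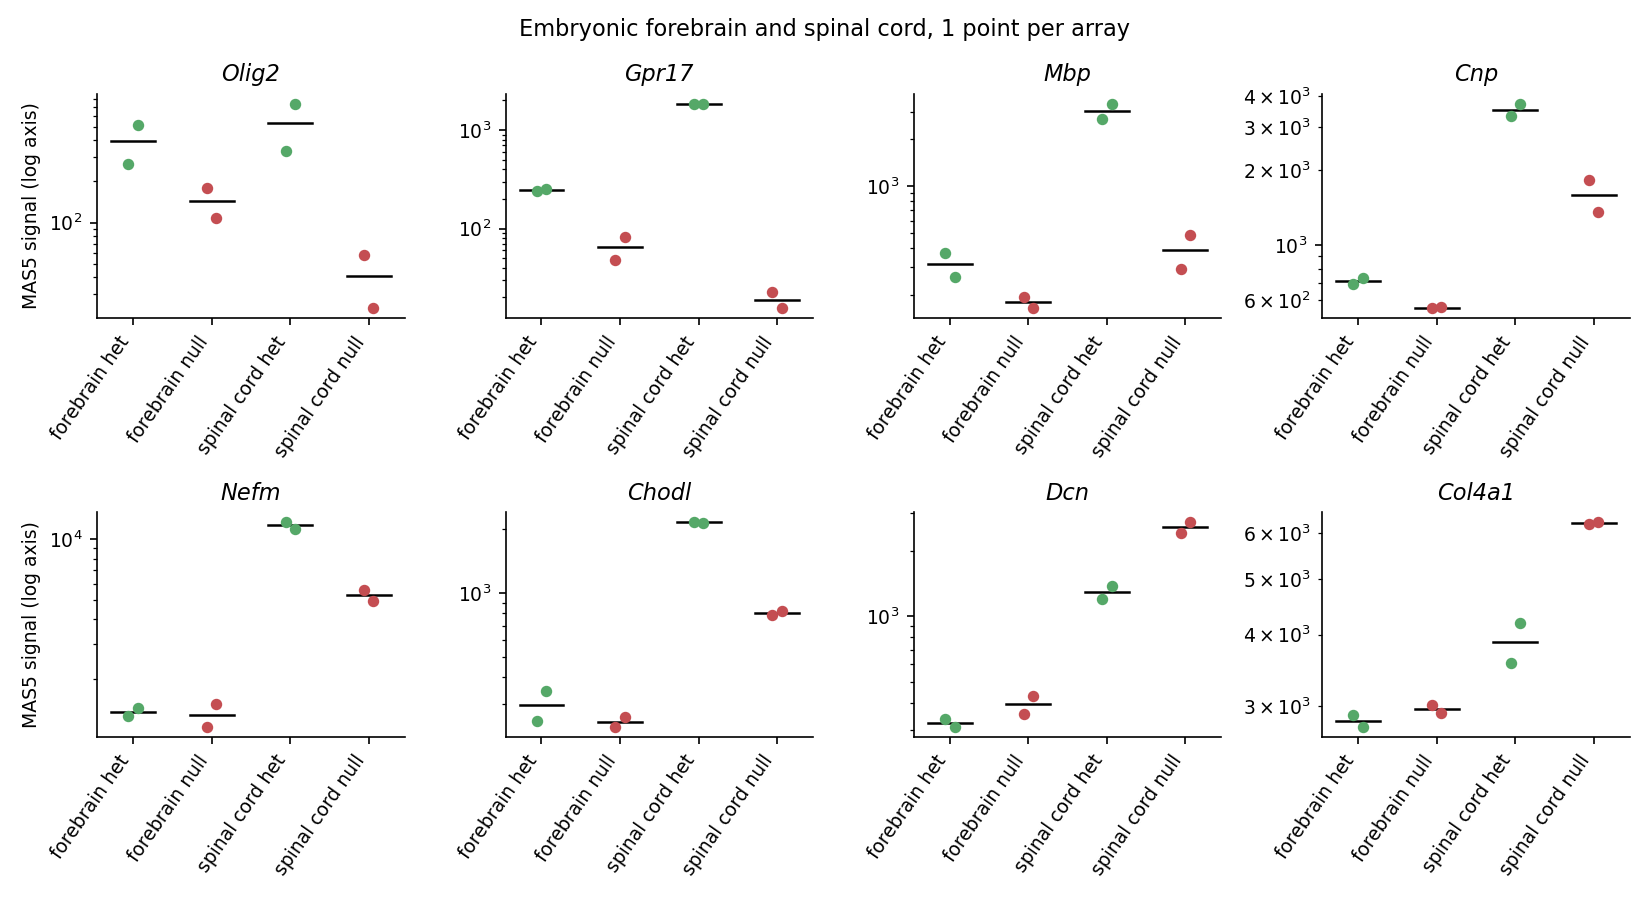
Array signal (log axis) of 8 genes in heterozygous and null forebrain and spinal cord, with 2 embryos per group shown as points. In spinal cord the mean of Gpr17 is 1846 in heterozygous and 19 in null embryos.

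Oligodendrocyte precursor genes were lower as a list in null spinal cord (adjusted p 9.2e-12, and adjusted p 0.172 with an estimated correlation), with 1 of 22 down, 0 up and 21 with no call, and 10 down adjusted over the list alone. Myelin genes were lower too (adjusted p 1.6e-04, and adjusted p 0.190 with an estimated correlation; 2 fell, 0 rose and 9 had no call of 11; 4 down adjusted over the list alone). Proneural glioma genes were lower (0.014; 1 rose, 1 fell and 16 had no call of 18; adjusted over the list alone, 1 rose and 2 fell), as were EGFR and MAPK response genes (0.047; 0 of 19 called, 1 down adjusted over the list alone). With an estimated correlation these had adjusted p 0.190 and 0.361. Fibroblast and pericyte genes were higher (adjusted p 2.4e-09, and adjusted p 0.190 with an estimated correlation; 1 rose, 0 fell and 12 had no call of 13; 5 up adjusted over the list alone), Dcn among them. Mesenchymal glioma genes (5.3e-04; 0 of 18 called, 2 up adjusted over the list alone), microglial genes (5.8e-04; 0 of 11 called, 2 up) and endothelial genes (0.0031; 0 of 14 called in either way) were higher as well. With an estimated correlation these had adjusted p 0.190, 0.199 and 0.190 in that order.

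In forebrain 5 genes were called between null and heterozygous embryos, of which 4 rose and 1 fell. The probe set that stands for Sox11, a factor of immature neurons, rose by 2.61, from 3343 ± 690 to 20291 ± 406 (SD, n = 2 each), and was called without each array in turn. In spinal cord it rose by 2.19, and was at 2.04 with no call without null embryo 2. On the tissue arrays this probe set had a mean log2 signal of 11.31, below the 11.59 to 12.92 of the others, though the highest (12.34) over all 30 arrays. The other 5 Sox11 probe sets had a median difference of 0.16 in forebrain and -0.12 in spinal cord. The lysophospholipid acyltransferase gene Mboat2 rose by 1.28 in forebrain and 1.31 in spinal cord, and its other probe set was at -0.21 and -0.15. In forebrain its call ended without either null embryo (1.25 to 1.30 over all arrays left out), and in spinal cord without null embryo 2 (1.34). Hbb-b2, an adult haemoglobin gene, rose by 1.89, but was not called without any 1 of the 4 forebrain arrays or without the spinal cord of heterozygous embryo 3 or 4 (1.71 to 2.08 over all arrays left out). Hoxb3 fell by 2.69, from 213 ± 95.7 to 18.7 ± 10.9. Olig2 (-1.33, adjusted p 0.72) and Olig1 (-0.15) were not called. Without the trend 0 genes were called in forebrain, so the Sox11 call there ended too. Cell-cycle genes were higher as a list (adjusted p 0.049), with 0 of 22 called in either way, and at 0.903 with an estimated correlation. The count was 3 without the forebrain of null embryo 1, 10 without that of heterozygous embryo 3, and 2 without the spinal cord of heterozygous embryo 3 or 4, where Hoxb3 lost its call.

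No gene was called by limma for a null effect that differed between spinal cord and forebrain, and 705 genes had an unadjusted p under 0.05. The differences for Gpr17 (-4.01, adjusted p 0.15) and Mbp (-2.20) did not pass. As lists, oligodendrocyte precursor genes (adjusted p 6.5e-05; 0 of 22 called; 1 up and 2 down adjusted over the list alone) and myelin genes (0.0099; 0 of 11 called, 3 down) were more reduced in spinal cord, both with adjusted p 0.369 with an estimated correlation. Fibroblast and pericyte genes (2.8e-05; 0 of 13 called in either way) and invasion and angiogenesis genes (0.030; 0 of 19 called, 1 up adjusted over the list alone) had a more positive effect there. These also had adjusted p 0.369 with an estimated correlation. Without the forebrain of heterozygous embryo 4 the count was 2.

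The null effects in neurospheres and tissues were close to uncorrelated. Across 11074 genes, which are not independent replicates, Pearson's r was 0.0092 with forebrain and 0.012 with spinal cord. The forebrain and spinal cord null effects, from the same embryos, had an r of only 0.055 across 12342 genes. A low r with neurospheres therefore cannot tell unrelated effects from imprecise tissue estimates. Of 498 genes raised in null neurospheres 0 were called in either tissue by limma, where 782 genes in forebrain and 742 in spinal cord had an unadjusted p under 0.05. An unrelated set of that size would give 0.135 rises in forebrain, and 0.225 rises and 0.270 falls in spinal cord, so this count of 0 tells little. Of 449 lowered genes 2 fell in spinal cord, where 0.243 would come from an unrelated set. These were Olig1 and Olig2, the targeted genes of the series design, while the tissue labels name Olig2 alone. The fall of Olig2 followed from the genotypes. Whether that of Olig1 in tissue did so or was a downstream change cannot be told from the labels. The overlap is therefore no evidence of a shared downstream effect. Id4 was at 8486 ± 1313 in null and 8422 ± 142 in heterozygous spinal cord (SD, n = 2 each).

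Spinal cord and forebrain of the same 4 embryos differed at 4939 genes, of which 2631 were higher in spinal cord and 2308 in forebrain. The posterior patterning genes Hoxc8 and Hoxd10 rose by 6.57 and 5.14 in spinal cord, and the sensory and motor neuron gene Sncg by 5.50. The choroid plexus gene Ttr fell by 6.89, the interneuron factor gene Dlx1 by 6.22, and the cortical factor genes Tbr1 and Fezf2 were at -5.72 and -5.08. Of 25 astrocyte genes 20 were higher in spinal cord, 2 lower and 3 without a call, and 21 and 2 adjusted over the list alone (adjusted p 2.1e-08, and adjusted p 0.136 with an estimated correlation), with the water channel gene Aqp4 at 3.82 and the connexin gene Gja1 at 2.67. Of 11 myelin genes 7 were higher, 0 lower and 4 without a call, with the same 7 and 0 counts adjusted over the list alone (adjusted p 0.0019, and adjusted p 0.138 with an estimated correlation), including Mbp (2.12). Lists of other cell types were higher in spinal cord too. Fibroblast and pericyte genes (adjusted p 1.2e-06; 10 of 13 higher, 0 lower and 3 without a call), microglial genes (8.7e-05; 9 of 11 higher, 0 lower and 2 without a call) and sensory ganglion and Schwann genes (0.0080; 4 of 6 higher, 0 lower and 2 without a call) had the same counts adjusted over the list alone. Each of these had adjusted p 0.136 with an estimated correlation. Of 13 forebrain interneuron genes 2 were higher, 10 lower and 1 without a call, and 2 and 10 adjusted over the list alone (adjusted p 7.7e-04, and adjusted p 0.136 with an estimated correlation). Of the 29 lists tested 13 passed, 8 of them higher, and the lowest adjusted p with an estimated correlation was 0.136. Endothelial genes passed with the embryo as a block (adjusted p 0.038, higher), and not without it (0.059), and in the blocked fit had adjusted p 0.331 with an estimated correlation. The Gapdh ratio ran from -0.22 to -0.07 in forebrain and from 0.04 to 0.37 in spinal cord.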

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

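The difference of the Olig2 effect between null and heterozygous lines was a planned comparison, and no test in this part was chosen after its result was seen. It passed the threshold for 7 genes. The null minus heterozygous difference was 4.17 for Hmga2, 3.82 for Olfml3 and 2.41 for Gpaa1. It was -3.36 for Itga8, -2.71 for Ptprd, -1.43 for Dipk2a and -1.36 for Lrpap1. In the null lines the Olig2 effect on Hmga2 was 3.91, on Olfml3 3.14 and on Itga8 -3.44, and in the heterozygous lines it was -0.26, -0.68 and -0.08. Hmga2 was high in heterozygous GFP cultures (2989 ± 686, SD, n = 2) and low in null GFP cultures (196 ± 64.4, SD, n = 3).

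Among the 6 untransduced null cultures, 1 array lay far from the others for the protocadherin gene Pcdh7. Its log2 signal was 4.20 in line 16, against 5.49 to 5.98 in the other cultures. For Pcdh7 these are signals of 2.4 and of 28.8 to 47.2, all below the array medians of 151.4 to 179.6. The size of the gap on the log2 scale depends on the 16 added to each signal, so it is no evidence of a culture that differs in Pcdh7. Of 63 values tested in this way 1 stood out, where 3.15 would by chance.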

How the results depend on the processing

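The term for sex, the untransduced control, the Gapdh covariate and the removal of chromosome 15 were chosen only after the values were seen, and the other settings were planned. Of 5362 recomputed values of 219 gene results, 4874 kept their direction and side of the threshold, 460 lost the call, 10 gained one and 18 changed sign. In number, the most calls were lost without the trend (52 of 219), with a log2 difference of at least 1 required (31 of 219), and with the Gapdh covariate (27 of 73). The 219 and 73 also count values that were not called in the main fit, so these are not shares of calls. Untransduced null arrays as the control ended 16 calls among 42 values, of which 40 were called in the main fit. The causes were not tested, except that counts with all probe sets are over more features and a required difference can only remove calls. A left-out array leaves fewer arrays, but some counts rose without an array.

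Testing all probe sets gave 1693 calls for null against Olig-expressing, 1396 against wild-type and 687 against heterozygous neurospheres, 381 with GFP, 2045 for Olig2 in null lines, 14 for the difference of the Olig2 effect, 2 for heterozygous against wild type, 1 for the difference between tissues and 9763 for spinal cord against forebrain. A log2 difference of at least 1 left 315, 326 and 215 for the null comparisons in that order, 397 for Olig2 in null lines, 2 for heterozygous against wild type and 1033 for spinal cord against forebrain. Without the trend the counts were 93 for null against heterozygous with GFP, 384 for Olig2 in null lines, 3 for the Olig2 difference, 1 in spinal cord, and 0 for the vector, for forebrain and for heterozygous against wild type. With the Gapdh covariate the counts were 227 for Olig2 in null lines, 90 for null against heterozygous with GFP and 3 for the Olig2 difference. Array weights gave 326 for null against heterozygous with GFP, 16 for the Olig2 difference, 5 for the vector and 3 in forebrain. A 2-group fit gave 567 for Olig2 in null lines and 1 in forebrain, and untransduced controls gave 380 for Olig2 in null lines. Without the array of farthest A260/A280 ratio the count was 527 for Olig2 in null lines and 1 for the vector. The block gave 4 for the Olig2 difference and 0 for the vector. A pseudocount of 64 gave 17 for the Olig2 difference and 1 for the tissue difference. Leaving out cross-hybridising probe sets gave 1 for the tissue difference and 1 for heterozygous against wild type. No filter gave 3 in forebrain and 0 for heterozygous against wild type, where 75th percentile scaling gave 1 and the sex term 2. Quantile normalization gave 5 for the vector. With an estimated correlation camera gave 0 list calls, against 46 with the preset one.

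The correlation between the null and Olig2 effects was -0.445, and -0.536 with the 75th percentile filter, -0.481 with array weights, -0.301 with no filter and -0.405 without the lines shared by both. The null effect in neurospheres against forebrain gave -0.0179 with that filter, 0.0039 with all probe sets, 0.0167 with array weights and 0.0019 with quantile normalization. Against spinal cord it gave 0.0168 with that filter, 0.0172 with array weights and 0.0193 without cross-hybridising probe sets.

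Leaving out each array in turn, where a group left with 1 array is assumed to vary like the others, gave these ranges. Null against Olig-expressing ran from 762 to 954, against wild-type from 478 to 828, against heterozygous from 242 to 442, and with GFP from 41 to 304. Heterozygous against wild type ran from 0 to 8. Olig2 in null lines ran from 304 to 1171, in heterozygous lines from 0 to 4, their difference from 1 to 34, and the vector from 0 to 5. Forebrain ran from 2 to 10, spinal cord from 2 to 21, their difference from 0 to 2, and spinal cord against forebrain from 4187 to 4557. List calls ran from 41 to 61. The correlation with the Olig2 effect ran from -0.489 to -0.403, with forebrain from 0.00096 to 0.0187 and with spinal cord from 0.0047 to 0.0180.

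Leaving out cross-hybridising probe sets turned Ly6e to 0.052 for Olig2 in null lines and Masp1 to 0.11 in null against heterozygous neurospheres, from -3.32 and -2.41 with another probe set of each gene. The other sign changes were of values that had not been called. For the tissue difference Cdkn1a ran from -0.15 without the spinal cord of null embryo 1 to 0.25 without that of null embryo 2, with -0.04 without the forebrain of heterozygous embryo 3. For the vector it ran from -0.037 without untransduced line 15 to 0.23 without line 11, with -0.0044 without line 12. For heterozygous against wild type it ran from -0.23 without wild-type line 2 to 0.17 without wild-type line 3, with 0.05 without heterozygous line 15 and 0.0073 with array weights. For Olig2 in heterozygous lines it ran from -0.088 without the Olig2 array of line 15 to 0.14 without that of line 11. For the tissue difference Id4 ran from -0.28 without the spinal cord of null embryo 1 to 0.032 without that of null embryo 2. In spinal cord Id4 ran from -0.16 to 0.16 without the same embryos, with -0.01 without heterozygous embryo 4, -0.011 with 75th percentile scaling and -0.029 with quantile normalization. For the vector Olig1 ran from -0.035 without GFP line 13, the array of farthest A260/A280 ratio, to 0.25 without GFP line 12. For the difference of the Olig2 effect the Olig2 signal ran from -0.51 without Olig2 line 14 to 0.070 without Olig2 line 12. Signal over background limits genes near the floor, where the pseudocount sets the size of a difference.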

Other observations

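Chosen only after the result was seen were the tests on chromosome 15 other than that of its runs of genes, those on Sox11 and Mboat2, and those on the Olig2 calls in null lines. Of the lists that did not pass between null and Olig-expressing neurospheres, some members were called. Of 20 EGFR and MAPK response genes 4 rose and 0 fell, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p 0.0551, and 0.523 with an estimated correlation), with Dusp4 at 1.94. Among 15 cyclin-dependent kinase regulators Cdk6 fell by 1.70 and Cdkn2b, a neighbour of the deleted Ink4a/Arf, rose by 0.73. Of 16 invasion and angiogenesis genes 2 rose and 2 fell, also adjusted over the list alone (adjusted p 0.936). The angiogenic ligand gene Angpt1 rose by 1.40 and the matrix gene Sparc by 0.90, while the protease inhibitor gene Timp3 fell by 0.94. The Notch genes Notch2 and Jag1 rose by 0.85 and 0.76. Of 26 genes near Olig1 and Olig2 0 rose and 2 fell, Il10rb (-1.20) and Atp5o (-0.53), and 1 rose and 3 fell adjusted over the list alone (adjusted p 0.106, and 0.245 with an estimated correlation).

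Other groupings of the same arrays were fitted as 2 groups. For null against Olig-expressing cultures the real grouping called 966 genes and was the 1 of 100 groupings to call as many. The highest other called 5, so chance is unlikely, at the smallest share that 100 groupings can give. The real grouping was also 1 of 84 against wild type (723, highest other 32) and 1 of 84 against heterozygous cultures (404, highest other 69). Chance is unlikely there too, again at the smallest share possible. Such groupings cannot address a trait that goes along with genotype, such as sex. For heterozygous against wild-type cultures the 10 groupings are too few for a share under 0.05 (real 3, highest other 1). The same holds for Olig2 in null lines (real 567, highest other 0), including the 4 groupings that part all 3 pairs of arrays from a line.

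Genes of chromosome 15 sat higher on 7 of the 22 neurosphere arrays, by a median of 0.14 to 0.26 over 405 genes, while the other neurosphere arrays ran from -0.13 to 0.05 and tissue arrays stayed within 0.011 of the median. The median of the autosomal genes was first subtracted on each array. In these 7 arrays the largest shift of another autosome was then 0.0315 in size, so among autosomes chromosome 15 stood apart. Since the subtraction removes a shift shared by all chromosomes, this cannot test an array-wide signal or RNA quality difference. In 3 groups some arrays showed the shift and others did not, which argues against genotype or transgene as the whole cause. The 7 were untransduced null lines 14 and 16, null GFP line 12, null Olig2 lines 12, 13 and 14, and heterozygous Olig2 line 15. They lean to null cultures and to the Olig2 virus, so a part for genotype or transgene stays open. At least 9 of 10 runs of genes along the chromosome were above the median in each of the 7 arrays, as a gain of the chromosome in part of the cultures could give, but an array without the shift also reached 10 of 10, so this test was weak, and a gain stays an open candidate. Passage in culture was not stated per array and was not tested.

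The Sox11 and Mboat2 probe sets rose in null tissue of both kinds, and 5 tested genes lie between these neighbours on chromosome 12. Soga3 on chromosome 10 was also called in both tissues, at 0.64 in forebrain and 0.76 in spinal cord. Its other probe set was at 0.52 and -0.21, and its forebrain call ended without any 1 of the 8 tissue arrays. Of the 3 genes called in both tissues Sox11 and Mboat2 are a pair, and 1.16% of 10000 random sets of 3 genes held a pair as close. Since their closeness prompted the test, chance neighbours cannot be told apart from a shared cause by it. The other probe sets of Sox11 and Mboat2 had medians of at most 0.21 in size. That is what a strain variant under the called probes may give, since the background was mixed. Other Sox11 probe sets ran from -0.71 to 0.47, and a change in transcript ends, or an effect of the Olig genotype on 1 form of the transcripts, stays open and was not tested.

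To weigh RNA quality as a cause of the Olig2 calls in null lines, for each line 200 genes were chosen by Olig2 against GFP in the other lines, and Olig2 was then set against the untransduced array of that line, so that no array served both. The median ratio of the differences was 0.781 in line 12, 0.858 in line 13 and 0.300 in line 14, with 95%, 96% and 81% of the same sign, against 69.4%, 62.2% and 56.1% of all genes, which argues against lower RNA quality of the GFP arrays as the whole cause. Without GFP line 13, which had an A260/A280 ratio of 2.83, 527 genes were called, against 554 without GFP line 14 and 304 without Olig2 line 12, which argues against that array as the whole cause, by a limit set with 527 known. Without chromosome 15, where 6.22% of genes rose against 3.12% elsewhere, 939 genes were called. With the Gapdh ratio as a covariate 227 genes were called, and 380 against untransduced arrays. For the Gapdh term itself 2 genes were called. Part of the calls from RNA quality stays open, given these lower counts. In line 14 the median ratio was also low against that line's own GFP array, at 0.523, with 0.773 in line 12 and 0.967 in line 13. The 0.300 in line 14 therefore cannot be put down to RNA quality alone. An effect of Olig2 remains a hypothesis.

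Within the 6 Olig-expressing untransduced cultures, Id4 might follow the astrocyte genes. Spearman's rho of Id4 with the mean of 25 astrocyte genes was 0.943 (exact permutation p 0.0167, two-sided) and Pearson's r was 0.728 (exact permutation p 0.101). The Id4 means of the wild-type and heterozygous cultures lay below the lowest array medians of these groups, 166.9 and 157.2. Both coefficients thus rest on low signals of Id4. Without the 2 cultures farthest from the median of Id4, r was 0.369 and rho was 0.8 over the 4 left, which are too few to tell whether the relation rests on those samples. It was the 1 relation of this kind computed.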
